A study of Danio rerio with 4 samples.

How the data were processed

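Poly-A selected RNA from dissected zebrafish retinas at 48 hours post fertilization was sequenced in 4 libraries, with 1 microgram of total RNA per condition, per the labels' protocols. The labels give 2 groups of 2 biological replicates, a control group that received the Id2aMM morpholino and a group that received the id2a morpholino. A morpholino is an antisense oligonucleotide that blocks translation or splicing of its target. The labels do not say how many embryos went into a library.

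The authors aligned the reads to zebrafish cDNA of Ensembl release 66 with bowtie, as far as the names of the deposited files say; versions, settings and the genome build are not given in the sources used here. The deposited table of each library holds whole-number counts of alignments per transcript, 1 column for 1 mate and 1 for both mates, per the file headers. The same deposited tables hold estimated counts in which each read is split over the transcripts it hits, per the file headers and the fractions found in the values. The authors also deposited a whole-series table that is called raw by its name but holds a score: each value equals 1000 times the RPKM of the counts of both mates, rounded. Transcript lengths for this check were solved from the same values over all libraries and rounded, so the lengths themselves were not checked independently. Recomputed this way, 98.8% to 99.7% of its 43156 values per library came out within 1 unit. Of 14238 solved lengths with high values, 71.0% lay within 0.1 nucleotides of a whole number. The authors' deposited comparison gives the same scores, a log2 fold change and an adjusted p-value for 43155 transcripts, from DESeq per the submitters' processing notes, with no version given.

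The plan fixed before the data were examined took counts from the whole-series table, or from the tables of single libraries if it held none. Because that table held scores, the counts of 1 mate per transcript were used, so what had been listed as an alternative became the main analysis. Each alignment counts in full, at 1.89 to 2.01 hits per read, so transcripts of 1 gene and near-identical paralogs share reads and their values are uncertain. Total counts were 50230438 and 53652256 in control replicates 1 and 2, and 42980929 and 54710062 in knockdown replicates 1 and 2, over 46226 transcripts of 26355 genes. Gene symbols came from the authors' table for 43155 transcripts, from another transcript of the same gene for 740 and from a reference list of gene names for 1531, and 800 had none.

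The groups were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F-test, no block), with Benjamini-Hochberg adjustment over 37012 transcripts of 20875 genes and a threshold of 0.05. A gene counted as changed if at least 1 transcript passed, with the direction of its transcript with the smallest p, which also stands for the gene wherever it is named. Levels are CPM on the TMM scale, as mean ± SD over the 2 libraries of a group. The SE beside a log2 fold change was derived from the test, as its absolute value over the square root of F. It is not a spread between libraries. Where a group holds 1 to 3 counts in all, a ratio is given with its exact 95% conditional binomial interval, and a list's median is also given with members at 0 counts in a group set to their bound, from a floor of 3 counts over the group. These intervals and floors cover counting error only. The 36 gene lists and the rule for naming genes were fixed with that plan. Of 1489 symbols written, 1360 matched. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on the most abundant transcript of each gene, adjusted over the lists, and again with an estimated correlation and with fry. Beside each count over all genes, a count adjusted over the list alone is given. A list's median per library, or between libraries, covers only its members averaging at least 2 CPM.

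The rule took id2a, then the 12 largest and 12 smallest log2 fold changes among called genes with an average of at least 2 CPM, separated groups and a symbol that is not a clone name, then up to 4 members per list by p, and every called member of the Notch and Id lists. Other members named beside a list's count were chosen after their values were seen. Results for 1 of the lists and 3 of the genes are not reported here.

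The methods were tested on simulated data for the knockdown against control comparison, with 37012 transcripts and 200 changed transcripts in each of 5 simulations, under 3 models of the dispersion. With dispersions on the trend, edgeR recovered 71.2% of 4-fold and 12.6% of 2-fold changes, and 3.23% of its calls were false. With each transcript's own estimated dispersion it recovered 65.2% and 8.0%, and 13.5% of its calls were false, above the nominal level. With dispersions drawn around the trend at the estimated prior of 6.05 degrees of freedom it made 0 calls, as did limma-voom, whereas DESeq2 1.42.0 made 866 calls of which 57.2% were false. A first run, with 1 simulation of the second model, had shown the excess, and the other models and further simulations were added after it; the main test was kept. The adjusted p-values may therefore be too small for transcripts more variable than the trend. In a simulation with the photoreceptor list lowered 2-fold, camera called that list and 0 of 34 unshifted lists. For the lowered list the adjusted p was 0.221 with an estimated correlation and 0.176 with fry. The simulated transcripts varied independently, so the simulation does not test camera where genes of a list vary together. In the real data the estimated correlation ran from -0.018 for interferon genes to 0.667 for epidermis and cornea genes.

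Alternatives in the plan were 2 other scalings and library size only, no filter and a stricter one (5 CPM in 2 libraries), DESeq2, limma-voom, a replicate block, each library left out, reads split and summed per gene, and thresholds of 0.10 and 0.01. Counts of both mates, split reads per transcript, and limma on log2(score + 1) were added after seeing the data.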

Results

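The transcriptome of zebrafish retinas at 48 hours post fertilization was measured in 2 control libraries and 2 id2a knockdown libraries. Id2a is a helix-loop-helix protein that lacks a DNA-binding domain and binds E proteins. Libraries held 42980929 to 54710062 counts. The comparison asks which transcripts differ when retinas develop with the id2a morpholino. Log2CPM correlated across transcripts, which are not independent, at 0.967 between the control libraries and 0.967 between the knockdown libraries, against 0.899 to 0.947 between groups.

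The targeted transcript was not lower in the knockdown. The id2a transcript with the smallest p (chromosome 17 in the authors' table) was at 32.7 and 20.8 CPM in the control libraries and at 41.6 and 36.8 CPM in the knockdown libraries, a log2 fold change of 0.55 (SE 0.27, edgeR adjusted p = 0.231). The other tested id2a transcript had a log2 fold change of 0.13 (SE 0.24, edgeR adjusted p = 0.768). The labels do not say whether the morpholino blocks translation, which leaves the transcript in place, or splicing, which may lower or alter it, so these levels leave the labels unchecked.

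Of the tested genes, 32 of 81 photoreceptor, 39 of 68 synaptic and excitability and 25 of 44 epidermis and cornea genes fell in the knockdown, while 10 of 67 G1/S and replication genes and 22 of 72 lens genes rose; the others did not pass. Each of these 5 lists was called by camera at a preset correlation, and each call was lost with an estimated correlation (adjusted p = 0.672 for each). With an estimated correlation, camera also missed the list lowered 2-fold in the simulation (adjusted p = 0.221). A call lost in this way cannot show a list to be unchanged. The rod opsin gene rho had a log2 fold change of -9.57 and the synaptic vesicle gene sypb of -3.01, against 1.21 for the cyclin gene ccnd1 and 2.96 for the lens crystallin gene cryba1b (n = 2 each). In all, 1683 of 20875 tested genes (2603 transcripts) passed, 494 higher and 1189 lower. The calls lay close to the threshold: the smallest adjusted p was 0.00390, 7 genes passed at 0.01 and 3812 at 0.10. In simulated data with 200 changed transcripts, 13.5% of calls were false with each transcript's own dispersion and 3.23% with dispersions on the trend. With drawn dispersions 0 calls were made. Such a share depends on how many transcripts truly change, so it cannot be read as the share among the real calls. The count rested on single libraries, being 0 without control replicate 1 (8160 transcripts at an unadjusted p under 0.05), 259 without control replicate 2, 1320 without knockdown replicate 1 and 3056 without knockdown replicate 2. It was 3313 with DESeq2, 3176 with no filter, 1004 with the stricter filter and 0 with limma on the log2 scores (10502 at an unadjusted p under 0.05). Of the 101 called genes named by rule, 101 lost their call without control replicate 1 and 68 without control replicate 2, with 0 changes of sign among them, and the fold change of 36 moved by over 1.5 times without at least 1 library.

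Photoreceptor genes made up 6 of the 12 largest falls among the named genes. Of 81 tested photoreceptor genes, 32 fell, 0 rose and 49 did not pass (52 fell when adjusted over the list alone), with a median log2 fold change of -1.87. The rod opsin rho went from 48.1 ± 1.25 to 0.0544 ± 0.0769 CPM (n = 2 each), a log2 fold change of -9.57 (SE 0.58, edgeR adjusted p = 0.00390). The rod transducin subunit gnat1 fell by 6.74 on the log2 scale, the red cone opsin opn1lw2 by 6.15, and the arrestins saga and sagb had log2 fold changes of -6.27 and -5.36. Transducin subunit gngt1 held 2 counts over both knockdown libraries, 277-fold fewer than in controls (interval 76.3 to 2290). The list was lower than other genes by camera (adjusted p = 1.94e-29), with an adjusted p = 0.672 with an estimated correlation. Over the 47 of 81 list members averaging at least 2 CPM, the knockdown libraries stood apart. Their medians against control were -2.43 in replicate 1 and -1.33 in replicate 2. Without knockdown replicate 1, which held 0 counts of them, log2 fold changes were -8.74 for rho, -5.89 for gnat1 and -5.43 for saga; without knockdown replicate 2 they depend on the prior count.

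Of 27 bipolar cell genes 12 fell and 0 rose (18 adjusted over the list alone), among them gnao1b (-2.32) and pcp4l1 (-4.22, log2 fold changes). Of 33 amacrine and horizontal cell genes 15 fell and 2 rose (24 and 2 adjusted over the list alone). The calcium-binding calb2b had a log2 fold change of -4.81 (SE 0.82), and gad1b, an enzyme of GABA synthesis, went from 8.24 ± 0.271 to 2.61 ± 0.154 CPM (n = 2 each), whereas the glycine transporter slc6a9 and tkt rose. Of 43 ganglion cell genes 19 fell and 0 rose (30 adjusted over the list alone), including pou4f1 (log2 fold change -2.76). Of 68 synaptic and excitability genes 39 fell and 0 rose (55 and 1 adjusted over the list alone), with the synaptic vesicle gene sypb falling from 25.5 ± 8.89 to 3.15 ± 1.34 CPM (n = 2 each). In these 4 lists, camera adjusted p-values were 1.26e-09, 2.00e-09, 1.52e-14 and 3.44e-23, in that order, and each had an adjusted p = 0.672 with an estimated correlation. Medians against control in knockdown replicates 1 and 2, over members averaging at least 2 CPM, were -2.78 and -1.49 for bipolar genes. They were -1.89 and -1.18 for amacrine and horizontal and -1.67 and -1.15 for ganglion cell genes. Log2 fold changes without knockdown replicate 1 and without knockdown replicate 2 were -4.00 and -6.96 for calb2b, -3.46 and -5.99 for pcp4l1 and -2.25 and -3.58 for pou4f1. Without control replicate 1 they were -4.13, -3.48 and -2.06. Of 29 neurogenic transcription factors 5 fell and 0 rose (13 and 1 adjusted over the list alone), namely neurod, neurod2, bhlhe23, scrt2 and MYT1 (1 of 2). That list was lower by camera (adjusted p = 0.000407, adjusted p = 0.675 with an estimated correlation), with medians against control of -1.17 in knockdown replicate 1 and -0.54 in knockdown replicate 2. Log2 fold changes without knockdown replicate 1 and without knockdown replicate 2 were -2.84 and -5.89 for bhlhe23, -1.30 and -2.49 for neurod and -1.28 and -2.47 for scrt2.

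**Figure D1:**
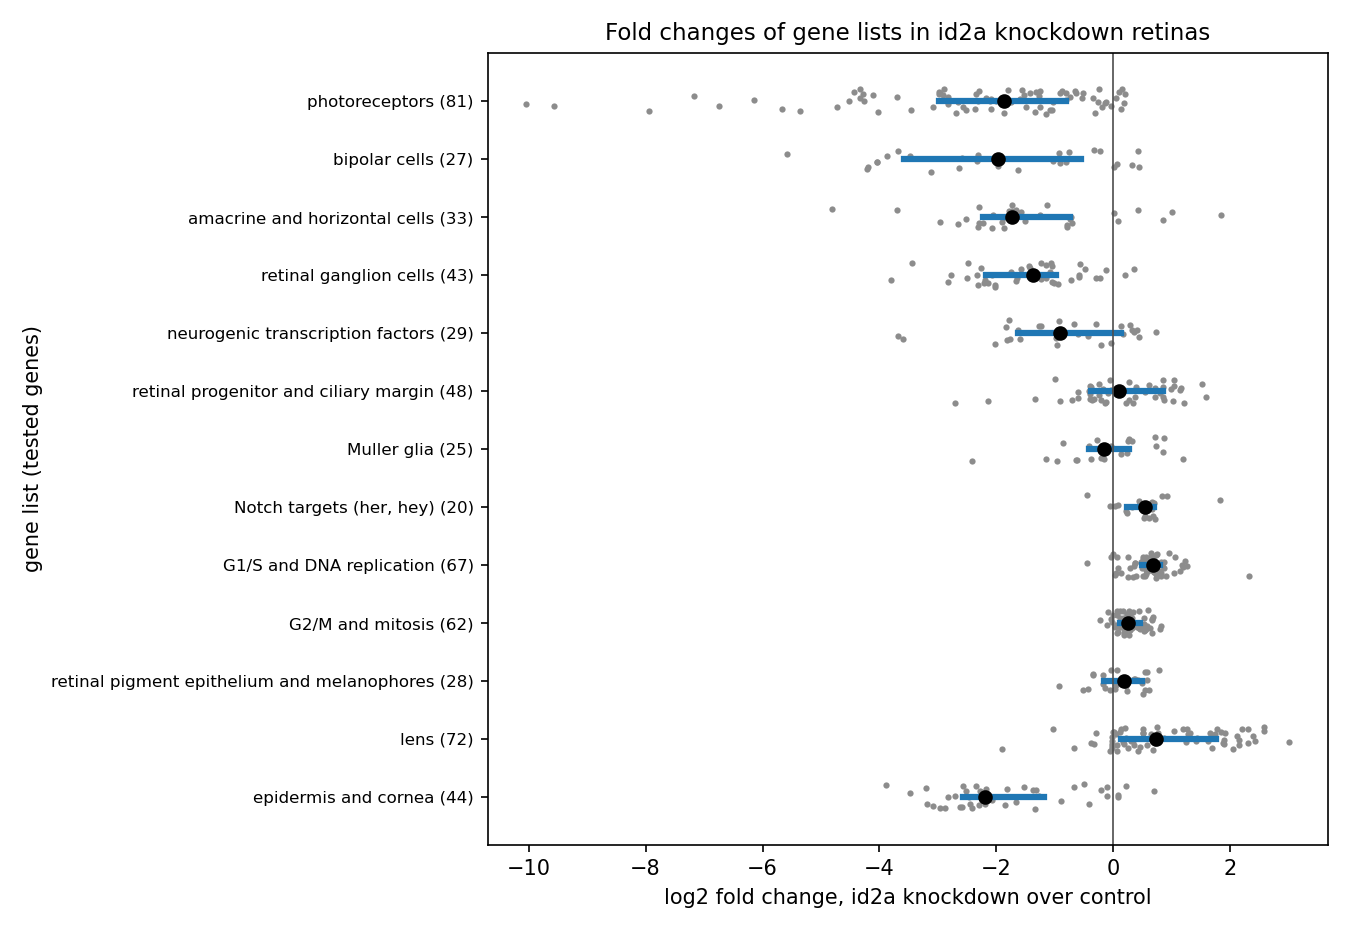
Log2 fold changes (x axis, id2a knockdown over control) of the tested genes of 13 gene lists (y axis, number of tested genes in parentheses). Grey points are genes by their most abundant transcript, blue bars run from the lower to the upper quartile and black points are medians, which lay at -1.87 for photoreceptors, -2.19 for epidermis and cornea and 0.74 for lens. Fitted values of 2 photoreceptor genes with no count in 1 group depend on the prior count; the list's median was -1.87 with these at their bound.

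Of 67 G1/S and replication genes 10 rose and 0 fell (32 adjusted over the list alone). The list was higher by camera (adjusted p = 4.95e-13, adjusted p = 0.672 with an estimated correlation). Cyclin ccnd1 went from 137 ± 23.9 to 317 ± 11.5 CPM (n = 2 each; log2 fold change 1.21, SE 0.22, edgeR adjusted p = 0.0270), and mcm7, of the replicative helicase, had a log2 fold change of 1.40. Of 62 G2/M and mitosis genes 0 passed with edgeR (0 adjusted over the list alone), with 17 higher and 0 lower at an unadjusted p under 0.05, 7 higher with DESeq2 and 1 with limma-voom. The list was higher by camera with a median of 0.26 (adjusted p = 0.000161, adjusted p = 0.675 with an estimated correlation). Of 48 progenitor and ciliary margin genes 7 rose (among them rx1, mycn, pax2a, nr2e1, foxd1 and fzd5) and rx3 fell (12 and 3 adjusted over the list alone). The transcription factor mycn went from 36.0 ± 6.84 to 91.6 ± 22.5 CPM (n = 2 each). The list did not pass (camera adjusted p = 0.0760), but passed upward without control replicate 1 (adjusted p = 0.0183), with reads summed per gene (adjusted p = 0.0105), with reads split per transcript (adjusted p = 0.0244) and with both mates (adjusted p = 0.0409).

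The 2 Notch lists and the Id list each held few calls. The list of Notch targets was written from transcription factors of the her and hey families, plus nrarpa and nrarpb, which belong to neither. Of its 20 tested genes her2 rose (log2 fold change 1.83, SE 0.33, edgeR adjusted p = 0.0267) and 19 did not pass. When adjusted over the list alone, 7 rose. Values for her4.1 and her4.2, uncertain because reads shared by such copies count in each, were 0.84 and 0.72 (edgeR adjusted p = 0.0583 and 0.0741). The list was higher by camera (adjusted p = 0.000368, adjusted p = 0.672 with an estimated correlation). Of 39 Notch receptor, ligand and processing genes the ligand jag1b rose (1.47) and 38 did not pass, with 0 by edgeR adjusted over the list alone. That list was higher by camera (adjusted p = 0.0432, adjusted p = 0.675 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.167), without knockdown replicate 2 (adjusted p = 0.227), with the stricter filter (adjusted p = 0.137) and with limma on log2 scores (adjusted p = 0.0688). Among 9 Id and E protein genes, the E protein gene tcf3 rose (0.94, edgeR adjusted p = 0.0419) and id4 fell (-1.66, edgeR adjusted p = 0.0441), the same 1 and 1 as adjusted over the list alone (camera adjusted p = 0.677, upward, with a median of 0.13 and a mean of -0.15). With reads summed per gene, id4 lost its call (edgeR adjusted p = 0.0535) and tcf3 kept it (0.0378). Of 6 tested tcf3 transcripts 1 passed. The value of id4 was -1.17 without knockdown replicate 1 and -2.39 without knockdown replicate 2.

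**Figure D2:**
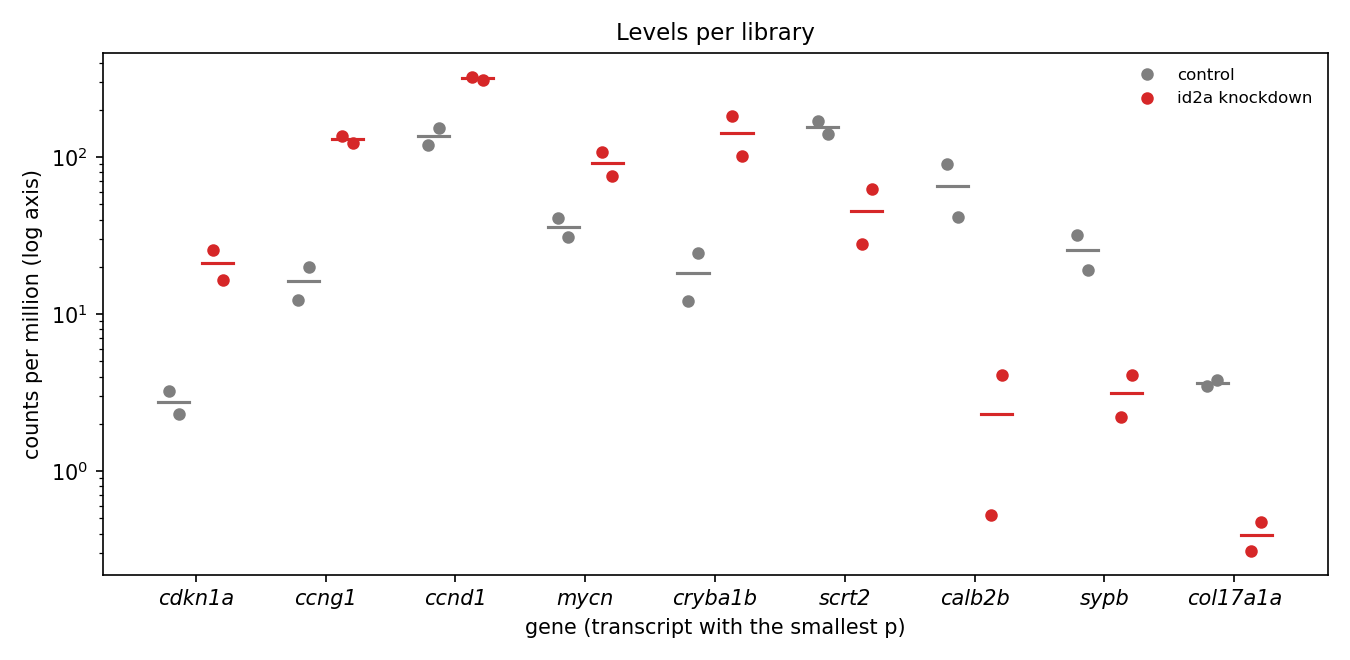
CPM (log y axis) of 9 named genes (x axis) in the 2 control libraries (grey) and the 2 id2a knockdown libraries (red), with group means as lines. Knockdown values lay above both controls for cdkn1a, ccng1, ccnd1, mycn and cryba1b, and below both for scrt2, calb2b, sypb and col17a1a.

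Markers of tissues around the retina also differed between the groups. Of 44 epidermis and cornea genes 25 fell and 0 rose (32 adjusted over the list alone). The list was lower by camera (adjusted p = 2.92e-18, adjusted p = 0.672 with an estimated correlation). Its medians against control were -1.61 in knockdown replicate 1 and -2.86 in knockdown replicate 2. The desmosome-linked cytoskeletal gene ppl stood at 27.7 ± 4.43 CPM in controls and 3.02 ± 1.87 CPM in the knockdown (n = 2 each). Of 72 lens genes 22 rose and 0 fell (28 and 1 adjusted over the list alone), with the crystallin cryba1b at 18.3 ± 8.62 and 143 ± 58.3 CPM (n = 2 each; camera adjusted p = 3.98e-13, adjusted p = 0.672 with an estimated correlation). The lens list was written with many crygm2d crystallin copies, and reads shared by such copies count in each, which makes its counts uncertain. Log2 fold changes of ppl were -4.00 without knockdown replicate 1 and -2.67 without knockdown replicate 2, and those of cryba1b 2.57 without control replicate 1 and 3.55 without control replicate 2. Of 53 periocular mesenchyme and matrix genes 3 fell (col6a1, col11a2 and COL9A1 (1 of 2)), with 0 adjusted over the list alone (camera adjusted p = 0.00102, adjusted p = 0.675 with an estimated correlation). Of 44 leukocyte genes HCLS1 and mpeg1 fell, also when adjusted over the list alone (camera adjusted p = 0.00460, adjusted p = 0.675 with an estimated correlation). The shares that fell in the mesenchyme (3 of 53) and leukocyte (2 of 44) lists were no higher than over all tested genes (1189 of 20875). The mesenchyme call was lost without control replicate 2 (adjusted p = 0.0721) and without knockdown replicate 2 (adjusted p = 0.0772), and the leukocyte call without knockdown replicate 2 (adjusted p = 0.214) and with the stricter filter (adjusted p = 0.430). Of 48 muscle genes 5 fell (5 adjusted over the list alone; camera adjusted p = 0.138), and of 28 pigment epithelium genes 0 passed with edgeR (2 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom, 0 adjusted over the list alone; camera adjusted p = 0.221). The muscle list passed downward with the stricter filter (adjusted p = 0.0342) and the pigment epithelium list upward without knockdown replicate 1 (adjusted p = 0.0149).

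The largest rise among named genes was that of rspo1, a secreted enhancer of Wnt signalling, from 0.0814 ± 0.115 to 5.81 ± 1.22 CPM (n = 2 each; log2 fold change 6.06, SE 0.77, edgeR adjusted p = 0.0198). The cyclin-dependent kinase inhibitor cdkn1a rose by 2.93 on the log2 scale, and the cyclin ccng1 went from 16.2 ± 5.44 to 129.9 ± 8.69 CPM (n = 2 each). Others among the 12 were fetub, hbbe3, cx44.1, lctla, RNF180 (1 of 2) and a transcript named BDP1 (2 of 2) by the authors and DAB2 in the reference list. Fetub stood at 8.61 and 0.417 CPM in the knockdown libraries, with log2 fold changes of 2.29 without knockdown replicate 1, 6.62 without knockdown replicate 2 and 6.71 without control replicate 2. That of rspo1 was 5.16 without control replicate 1, which held 0 counts of it, and without control replicate 2 it was 11.15, a value that depends on the prior count. Fetub, cx44.1 and BDP1 (2 of 2) lost their calls with reads summed per gene (edgeR adjusted p = 0.0534, 0.0606 and 0.0913). Among the 12 largest falls were also gnb3a, igf1, igsf21b, SLITRK6 and FAT1 (2 of 2).

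The authors' deposited table calls 3837 transcripts at an adjusted p under 0.05, 1380 higher and 2457 lower. Of 37003 transcripts tested in both, the authors' deposited table called 3682 and the present fit 2603. Called in both were 2058, all 2058 in the same direction, and both rest on the same libraries. Genes named above that the authors' table did not call included fetub (DESeq adjusted p = 0.4), cx44.1 (0.379), BDP1 (2 of 2) (0.196), jag1b (0.112) and pou4f1 (0.0894). The authors' deposited table gives id2a a log2 fold change of 0.61 with an adjusted p of 0.227.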

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

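The alternatives with both mates, split reads per transcript and limma on log2 scores were chosen after seeing the data. The id2a log2 fold change stayed above 0 and did not pass under any of the 16 alternative fits (0.26 to 0.94 with a library left out, the lowest without control replicate 2 and the highest without control replicate 1). The counts of genes changed, higher and lower (1683, 494 and 1189) became 3176, 1115 and 2061 with no filter, 1004, 309 and 695 with the stricter filter, which tests fewer genes, 3313, 1301 and 2012 with DESeq2, 3812, 1417 and 2395 at a threshold of 0.10, 7, 2 and 5 at 0.01, and 0, 0 and 0 with limma on log2 scores (smallest adjusted p 0.103); split reads gave 805 higher. With 1 library left out, they ranged from 0 to 3056, 0 to 1013 and 0 to 2043; the lone library is then assumed to vary like the other group. Simulations with control replicate 1 left out recovered 55.8% of 4-fold changes with dispersions on the trend, 61.6% with each transcript's own dispersion and 3.2% with drawn dispersions. With all 4 libraries these shares were 71.2%, 65.2% and 0%. In none of the 3 models did leaving the library out end the recovery of these changes. Each simulation held 200 changed transcripts, a number not matched to the real data. They therefore do not settle why the calls were lost without control replicate 1. Apart from these simulations, the causes were not tested. With each transcript's own dispersion, 36.4% to 39.0% of simulated calls were false with a library left out, 30.5% with the replicate block and 25.4% with DESeq2, against 13.5% in the main analysis. The replicate block gave 2324 genes (691 higher, 1633 lower) and ended the call of the clock list (adjusted p = 0.0530); deviations of same-numbered libraries correlated at -0.020, although the second principal component (16.4% of variance) parted the numbers, and with 2 pairs and no label the numbers were not taken as pairs. The 17 lists called by camera (7 up, 10 down) all lost their call with an estimated correlation and with fry (smallest adjusted p 0.672 and 0.232). Neither of these tests called the list lowered 2-fold in the simulation (adjusted p = 0.221 and 0.176). Their lost calls therefore cannot tell a changed list from an unchanged one. Over all alternatives, adjusted p ran from 0.00456 to 0.675 for Notch receptors, 5.46e-05 to 0.675 for leukocytes, 3.38e-07 to 0.675 for mesenchyme, 0.00361 to 0.675 for Hedgehog, 0.00954 to 0.675 for clock and 0.0105 to 0.675 for progenitor genes. Without knockdown replicate 1 the list of brain regions outside the retina turned from up to down (median -0.59, adjusted p = 0.0149; medians ran up to 0.45 with another library left out); the cause was not tested. Of the 101 called named genes, 101 kept their call with each other scaling, with DESeq2 and with the block, 99 with limma-voom, 92 per gene and 0 with limma on log2 scores.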

Other observations

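All tests of explanations in this part were chosen after the results were seen. Genes of retinoic acid metabolism moved both ways: of 31 tested, cyp1b1, cyp26c1, cyp26a1, aldh1a3 and crabp2a rose and rbp4, rargb and raraa fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.556, upward, with a median of -0.06 and a mean of -0.15). Of 39 clock-related genes 5 fell (per2, cry1a, rorab, nfil3-6 and aanat2) and DEM1, an exonuclease named EXO5 in the reference list, rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0460, adjusted p = 0.675 with an estimated correlation); that call was lost with reads summed per gene (adjusted p = 0.174), with reads split per transcript (0.150), with limma on log2 scores (0.0982), with the replicate block (0.0530), without control replicate 1 (0.167) and without knockdown replicate 1 (0.314). In the Hedgehog list cdon rose (1 of 22, 1 adjusted over the list alone; camera adjusted p = 0.0280, adjusted p = 0.675 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.209) and without knockdown replicate 1 (0.0571). Of 45 Wnt genes 4 rose (rspo1, tcf7l1b, tcf7l1a and fzd5) and apc fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0895, but 0.0125 without knockdown replicate 2 and 0.0440 with reads summed per gene).

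Of 54 stress genes fos rose and 5 fell, among them xbp1, calr and junb (5 and 9 adjusted over the list alone; camera adjusted p = 0.664). Of 25 Muller glia genes slc1a3a rose and icn, also an epidermal list member, fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.988). Of 18 genes of cell cycle exit cdkn1a and RBL2 rose and ccng2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.556, upward, with a median of -0.0017 and a mean of 0.07). Of 26 erythroid genes hbbe3 rose and cahz and klf4 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.399). In the ribosomal protein list, whose pattern also took in kinases, RPS27L rose and rpl22l1 and the kinase RPS6KA2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.176, but 0.0226 without control replicate 2 and 0.0343 with reads summed per gene). Of 34 histone genes h2afy2 and H2AFY2 (2 of 2) fell, with near-equal values that shared reads make uncertain (2 adjusted over the list alone; camera adjusted p = 0.0662, upward, but 0.0116 without control replicate 1, 0.00534 without knockdown replicate 1, 0.0386 with both mates, 0.0353 with no filter and 0.00279 with limma on log2 scores). Single genes fell in the endothelial (aplnrb, 35 tested), BMP (bmpr2a, 53), FGF (spred3, 29) and outer brain (gbx2, 37) lists, with 0 each adjusted over the list alone and camera adjusted p of 0.551, 0.393, 0.551 and 0.607; the FGF list had a median of 0.17 and a mean of -0.01. In the interferon (21), iridophore (13) and mitochondrial (13) lists 0 passed with edgeR over all genes, against 3, 3 and 5 at an unadjusted p under 0.05, 1, 1 and 2 with DESeq2, 0, 0 and 2 with limma-voom, and 0, 0 and 2 adjusted over the list alone (camera adjusted p = 0.920, 0.390 and 0.0713). The interferon test was upward with a median of -0.07, and the mitochondrial list passed downward with limma-voom (adjusted p = 0.0155), with the stricter filter (0.0384), without control replicate 1 (0.0308) and without knockdown replicate 1 (0.0343).

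The lower neuronal and photoreceptor lists (adjusted p = 0.672 with an estimated correlation for photoreceptors) were set against 3 explanations. Less retinal tissue in the knockdown samples, with no other change, would lower progenitor genes as well. The lower quartile of that list was -0.38, above the photoreceptor median of -1.87. A like fall of both lists is thus argued against. A smaller retinal share cannot be excluded, since a rise of progenitor genes (7 of 48 rose) could offset it. A loss by transcript length is argued against. The 4 retinal neuron lists kept at least 0.927 of their medians once the length trend was taken out. A general delay of development may lower genes of late-born cells more. The mean of the photoreceptor and bipolar list medians lay 0.55 below the ganglion cell median. The difference was -0.55 (95% bootstrap interval -1.14 to 0.15 over members, which are not independent). A delay therefore cannot be told apart from a lasting block here. Fewer differentiated cells, lower expression per cell and effects of the morpholino apart from the loss of id2a were not tested; no rescue or second morpholino is among the samples.

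Of the epidermis and cornea list 25 of 44 genes fell, and of the lens list 22 of 72 rose, while the others did not pass and both list calls were lost with an estimated correlation (adjusted p = 0.672 each). Less retinal tissue in the knockdown samples would raise both, but the lens lower quartile lay 1.31 above the epidermal upper quartile on the log2 scale. Uneven amounts of surface epithelium taken in dissection are a candidate explanation for the epidermal part: that list differed between the knockdown libraries by a median of -1.29 (replicate 2 minus 1), more than any of the other lists (at most 1.03, bipolar cells). Its most abundant member krt4 stood at 197 and 52.69 CPM in the knockdown libraries against 647 and 620 CPM in controls, and krt5 at 18.5 and 3.93 against 159 and 169.6 CPM. Of its 44 tested genes 2 are also in another list. A change of the surface epithelium in the knockdown stays open, as does the cause of the higher lens values.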
